A study of Homo sapiens with 4 samples.

How the data were processed

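RNA levels were measured on single-colour oligonucleotide arrays in KM-H2, an established human cell line derived from Hodgkin lymphoma. The 4 arrays fell into 2 groups of 2, cells transduced with a non-silencing control and cells transduced with a lentiviral hairpin vector aimed at the CIITA-BX648577 fusion transcript. Per the labels' protocols, the hairpin was directed at the BX648577 part of the fusion (vector name sh.FLJ27352), RNA was purified on Qiagen columns, and biotinylated cRNA was made by the standard Affymetrix single-cycle method. The deposited values are linear probe set intensities, 1 per probe set and array, for 54613 probe sets. How the authors made an intensity from the scanned probes is not given in the sources used here. The array means lay between 53.3 and 54.6 while the quartiles differed, so the values look scaled to a common level and not quantile normalized. Values at exactly 1, from 971 to 1080 probe sets per array, mark a floor, and 2 values of knockdown replicate 2 lay below it. The scanner files were not used here.

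Probe sets were named through the platform's annotation, in which 41091 had 1 gene, 1801 had several and 11721 had none, and only the first kind was named. Of these, 41037 matched a gene of the human annotation GCF_000001405.40 (GRCh38.p14) by gene number, and 0 symbols needed an update. The labels name no genome build, so no coordinates are given. BX648577 itself is not a name in that annotation. The link from FLJ27352 to the gene once called C15orf65 and now PIERCE2 is general knowledge and was not derived from the tables, and the place of its probe set relative to the fusion point is not known here. No control probe sets were among the rows, so the planned check of RNA quality from them was not run.

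The following choices were made before the data were examined. Intensities were turned into log2(intensity + 16), which understates the change of dim probe sets. Arrays would have been centred had their medians differed by over 0.2, and the medians spanned 0.07, so they were left as deposited. Each gene was represented by its probe set with the highest mean, and probe sets with a mean below the median of all probe set means (4.60 on the log2 scale, an intensity of 8.26) were left out, which left 12922 of 19775 named genes. Knockdown was compared with control in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, using 1 prior variance for all genes (called the common-prior fit), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A second fit, chosen at the same time, let the prior variance follow mean intensity (the intensity-trend fit). The other alternatives were other filters, quantile normalization, median centring, robust hyperparameters, every probe set or the mean of a gene's probe sets, pseudocounts of 1 and 64, thresholds of 0.01 and 0.10, a fold threshold, a block for the replicate number, and leaving out each array.

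A total of 23 gene lists was fixed, covering class II and class I antigen presentation, ligands of T cells, signalling and stress pathways, the cell cycle, Hodgkin and B cell genes, the RNA interference machinery and markers of 4 kinds of other cells. They were tested with limma's camera with a preset correlation of 0.01, two-sided and adjusted over the lists, with an estimated correlation and fry beside it. With an estimated correlation camera uses only the residual degrees of freedom, 2 for these 4 arrays. Hardly any of 23 lists could pass that form after adjustment, so failing it says little. Fry's directional p rests on the same 2 residual degrees of freedom, so the same limit holds for it. The genes named are the targets, the genes past the threshold in the common-prior fit (up to 12 per direction), up to 10 genes of smallest p per direction where fewer than 5 passed, the 2 members of each list with the largest moderated t where none passed, and 8 genes of antigen presentation and checkpoint biology. Other genes named below were chosen after their values were seen, mostly because they passed the intensity-trend fit.

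The scripts were tested on simulated data, with 200 of 12922 genes changed in 10 simulations of this comparison. The changed genes were drawn only from genes brighter than the median of those tested. Variances were drawn from the prior of the intensity-trend fit, with independent normal errors. The simulated data thus met that fit's assumptions and favoured it, and the recovery rates hold for brighter genes only. The common-prior fit recovered 6.12% of genes changed by 0.5 on the log2 scale, 98.2% of those changed by 1 and 100% of those changed by 2, with a median of 3 false calls. The intensity-trend fit recovered 80.6%, 100% and 100%, with a median of 9 false calls. With no gene changed, the fits made at most 0 and 1 calls. Camera found a shift of 0.2 in the class II list in 10 of 10 simulations with the preset correlation and in 7 of 10 with an estimated one. A pass was counted there on that list's own p, without adjustment over the fixed lists, and with independent errors. These rates therefore do not hold for the adjusted p-values used below. In particular, they do not make a failure of the estimated form informative. The labels call the arrays of a group replicates and do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and an exact permutation test of 2 against 2 arrays could not give a two-sided p below 0.333. Plots were drawn with matplotlib 3.10.9.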

Results

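Transcript levels of KM-H2 cells were compared between 2 arrays of cells carrying a non-silencing control and 2 arrays of cells carrying a hairpin against the CIITA-BX648577 fusion transcript. KM-H2 is a Hodgkin lymphoma line in which CIITA, the master activator of HLA class II transcription, is fused to the transcript BX648577. The comparison asked which genes differ once that fusion transcript is targeted. Mean intensities were 54.2 and 53.7 on the control arrays and 54.6 and 53.3 on the knockdown arrays, with medians of 9.17, 9.28, 8.37 and 8.12. Between 9.17% and 9.70% of probe sets on an array lay above an intensity of 100. Over all probe sets, the log2 values of the controls correlated with each other at r = 0.980, those of the knockdowns at r = 0.987, and arrays of different groups at r = 0.979 to 0.982. These correlations are across probe sets, which are not independent replicates. Levels below are mean intensities ± SD over n = 2 arrays per group, and fold changes are knockdown minus control on the log2(intensity + 16) scale.

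Cells with the hairpin had 66.3% of the control signal at the single probe set for the fusion partner and lost most of the signal of the non-coding RNA KIF23-AS1 and of one PLEKHG2 probe set. The HLA class II list had a median log2 fold change of 0.14, which passed camera with its preset correlation (adjusted p = 0.00629). That call was lost without the DRB genes (adjusted p = 0.146) and without knockdown replicate 2 (median 0.12). With an estimated correlation the adjusted p was 0.931, but hardly any list could pass that form with 2 residual degrees of freedom. The probe set of PIERCE2, the gene to which FLJ27352 corresponds, read 880 and 947 in the controls and 621 and 590 in the knockdowns. The group means were 914 ± 47.9 and 605 ± 21.4, a log2 fold change of -0.58 (SE 0.10). PIERCE2 did not pass the common-prior fit (limma adjusted p = 0.252) and did pass the intensity-trend fit (adjusted p = 9.74e-05). Whether that probe set reads the fusion, unfused transcripts or both is not known here. CIITA, whose probe sets read fused and unfused CIITA alike where their targets are kept in the fusion, stood at 62.4 ± 3.87 in control and 57.1 ± 4.98 in knockdown at its brightest probe set. Its log2 fold change was -0.10 (SE 0.11, adjusted p = 0.702). The other CIITA probe sets were dim, at 10.2 against 10.6 and 3.30 against 4.20. CCPG1, a neighbour of PIERCE2 in the GRCh38.p14 annotation, read 55.4 and 43.3 with a log2 fold change of -0.27 (adjusted p = 0.346).

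Only KIF23-AS1 and PLEKHG2 passed the common-prior fit, and both fell. KIF23-AS1, an RNA transcribed antisense to the mitotic kinesin gene KIF23, went from 91.9 ± 12.5 to 9.18 ± 1.05, a log2 fold change of -2.09 (SE 0.12, adjusted p = 0.00790). KIF23 itself read 45.5 and 50.5 (log2 fold change 0.13, adjusted p = 0.775). PLEKHG2 went from 135 ± 6.13 to 32.1 ± 2.52 at its brightest probe set, a log2 fold change of -1.65 (SE 0.10, adjusted p = 0.00790). Its other probe sets were dim and did not show this, with 10.2 against 13.5 and 11.7 against 11.3. Only 1 hairpin was used, so whether the falls of KIF23-AS1 and PLEKHG2 follow from targeting the fusion was not tested. No gene was called higher by limma's common-prior fit or its robust form, while 828 genes were higher and 993 lower at an unadjusted p below 0.05. Without control replicate 2 only KIF23-AS1 was called, without control replicate 1 PLEKHG2 gave way to SGO1, a gene bright on control replicate 2 alone, and without knockdown replicate 1 there were 6 calls. At 47.3% of tested genes both knockdown arrays lay on one side of both control arrays. An even share over the possible splits of the arrays would be 33.3%. All genes share the same arrays, so any difference between whole arrays moves this share, and the gap is no test against chance.

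**Figure D1:**
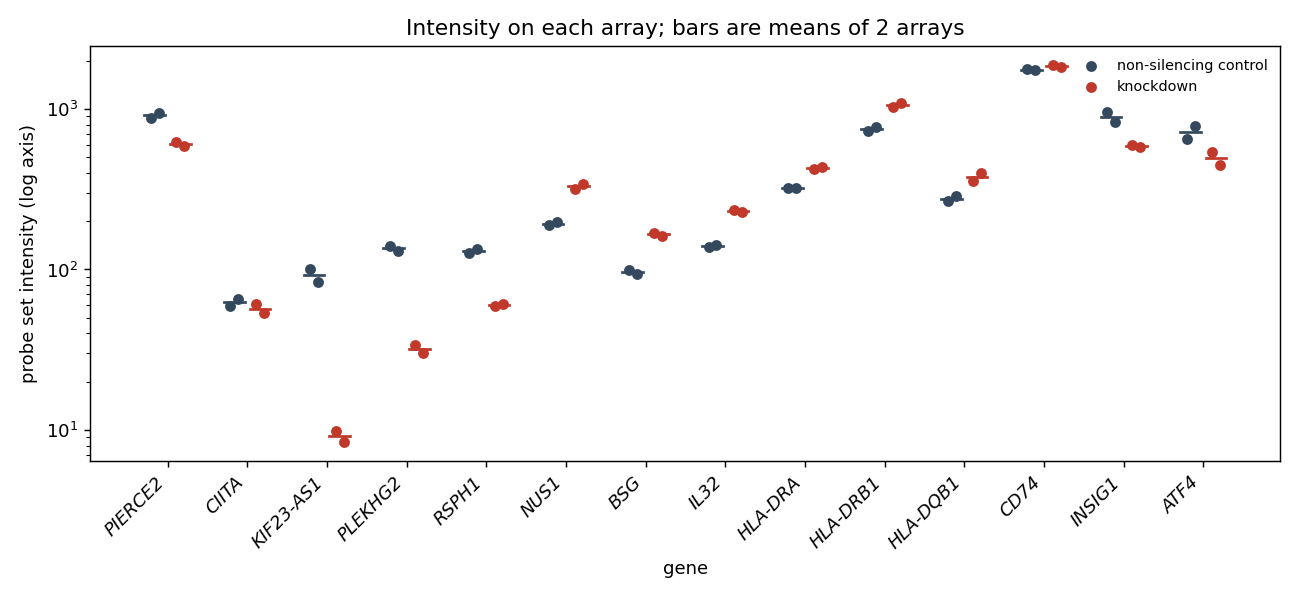
Intensity of 14 genes on each array (log axis), with controls in dark blue and knockdowns in red; points are single arrays and horizontal bars are means of 2 arrays. KIF23-AS1 and PLEKHG2 show the widest gap, PIERCE2 lies at 66.3% of its control level, and CIITA and CD74 differ little.

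The planned fit that let the variance follow intensity called 387 genes, 206 higher and 181 lower, both genes above among them. Most of these differences were small. Their median absolute log2 fold change was 0.43, and 4 of them reached 1 (KIF23-AS1, PLEKHG2, LOC101927157 and LINC02078, all lower). The count was 23 with the mean of a gene's probe sets, 83 with no filter, 143 without control replicate 2, 142 without knockdown replicate 2 and 1010 with the replicate number as a block. The balance was 484 higher and 128 lower with median centring, 157 and 190 with quantile normalization, and 119 and 258 without knockdown replicate 1. Among the 10 genes of smallest p in the lower direction were RSPH1, a component of the radial spokes of cilia, at 130 ± 5.76 and 59.9 ± 1.29 (log2 fold change -0.94), and the uncharacterised transcript LOC101927157, at 43.4 ± 4.38 and 6.86 ± 4.50 (-1.39). Both had an adjusted p of 0.147 in the common-prior fit, and of 6.68e-05 and 0.000149 in the intensity-trend fit. SLC2A5, a fructose transporter, stood at 51.1 and 26.0 (-0.68), CLDN18, a tight junction claudin, at 49.0 and 25.6 (-0.64), and LINC02525 at 53.7 and 27.3 (-0.69). HYDIN2, DHX9-AS1 and PCP4 were dim in both groups, with control means of 15.9, 17.1 and 18.5 and knockdown means of 3.05, 4.59 and 5.68. All of these lower genes passed the intensity-trend fit, with adjusted p-values up to 0.0389, and apart from KIF23-AS1 and PLEKHG2 none passed the common-prior fit.

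In the other direction, NUS1, a subunit of the enzyme that makes dolichol chains for protein glycosylation, stood at 193 ± 6.05 in control and 329 ± 15.4 in knockdown (log2 fold change 0.73, SE 0.10), and its other probe set read 82.8 and 146 (0.72). BSG, which encodes the surface protein basigin, stood at 97.1 ± 3.90 and 166 ± 4.28 (0.68, adjusted p = 0.000649 in the intensity-trend fit). IL32, a cytokine gene, stood at 140 ± 1.96 and 231 ± 4.53 (0.66), and LINC00621 at 162 ± 3.30 and 311 ± 29.2 (0.88). SERPINA6, the corticosteroid-binding globulin gene, read 45.8 and 104 (0.96), CSGALNACT1, an enzyme of chondroitin sulfate synthesis, 50.0 and 94.1 (0.74), and AOC1, a diamine oxidase, 19.2 and 47.3 (0.85). CIMIP6, LINC02532 and NLRP11 had control means of 3.37, 5.15 and 12.3 and knockdown means of 20.8, 18.7 and 35.2. Other probe sets went the other way for LINC02532, at 12.1 and 5.82 (-0.37), and for CSGALNACT1, at 13.8 and 9.87 (-0.20). All 10 passed the intensity-trend fit, with adjusted p-values from 3.00e-05 to 0.0301, and none passed the common-prior fit, where they ranged from 0.205 to 0.247.

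**Figure D2:**
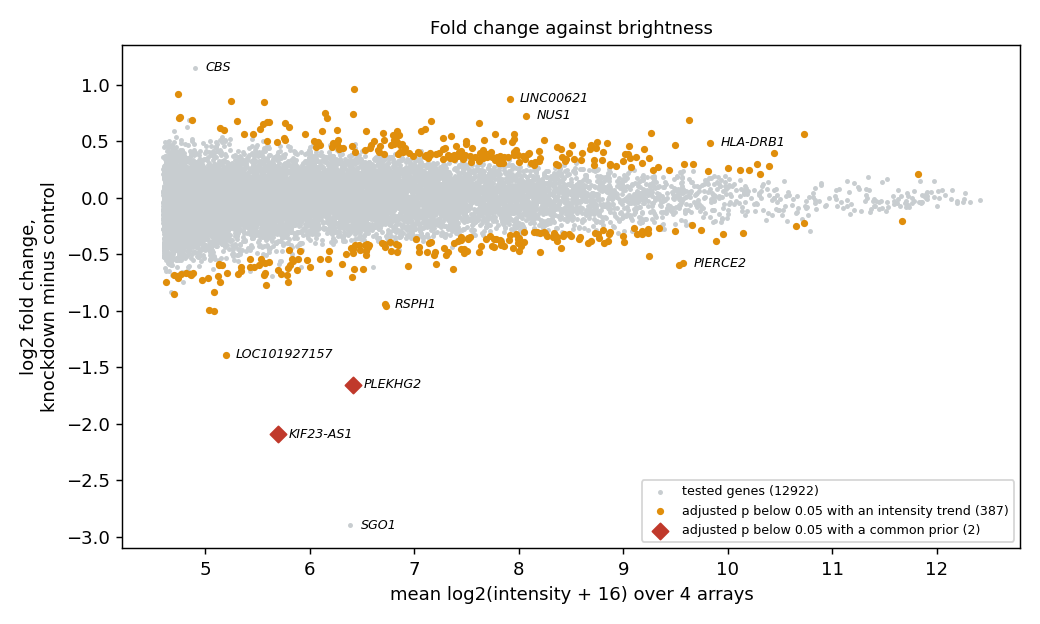
Log2 fold change (knockdown minus control) against mean log2(intensity + 16) over the 4 arrays for 12922 tested genes (grey), with the 387 genes past the intensity-trend fit in orange and the 2 past the common-prior fit as red diamonds. Most orange points lie within 1 log2 unit of 0, and SGO1 and CBS, far from 0, pass neither fit because their replicates differ.

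Of the 23 gene lists, only that of HLA class II genes passed camera with its preset correlation, and none passed with an estimated one. Of its 15 tested members, 13 lay above 0 and 2 below, with a median log2 fold change of 0.14 (quartiles 0.07 and 0.35), and the list rose against the other genes (camera adjusted p = 0.00629). With an estimated correlation the adjusted p was 0.931 (unadjusted 0.0603). The correlation estimated for this list, -0.03, lay below the preset 0.01, so it did not raise the p. That form has only 2 residual degrees of freedom, so its failure cannot tell whether the shift is fragile. Fry, which tests whether the members move one way on balance and makes no comparison with other genes, gave an adjusted p of 0.115. It called 0 of the 23 lists and rests on the same 2 residual degrees of freedom, so this failure says little too. HLA-DRB1 read 751 ± 31.4 in control and 1061 ± 39.0 in knockdown (log2 fold change 0.49, SE 0.10), and the pseudogene HLA-DRB6, whose sequence is close to that of the other DRB genes and whose own level is therefore uncertain, 39.4 and 62.3 (0.50). The HLA-DRB1 probe set is of a type whose probes can match related transcripts, so its level is uncertain as well. HLA-DRA, which encodes the DR alpha chain, stood at 323 ± 0.83 and 430 ± 10.1 (0.39), with 290 and 405 at its other probe set (0.46). HLA-DQB1 stood at 276 ± 13.9 and 378 ± 34.2 (0.43) at its brightest probe set, but at 293 and 294 (0.01), 156 and 162 (0.05) and 45.8 and 60.2 (0.30) at others, and all 4 are of a type whose probes can match related transcripts, so its level is uncertain. HLA-DQA1 stood at 406 ± 31.8 and 504 ± 49.7 (0.30). No class II gene passed the common-prior fit over all genes, 4 did when adjusted over the list alone (HLA-DRB1, HLA-DRB6, HLA-DRA and HLA-DQB1), and all 5 passed the intensity-trend fit, with adjusted p-values from 0.000315 to 0.0483. The other members passed neither fit. CD74, the class II invariant chain, read 1754 ± 18.1 and 1860 ± 36.0 (0.08), HLA-DPA1 1105 ± 95.4 and 1177 ± 33.3 (0.09), and HLA-DMA, a peptide loading factor, 118 and 132 (0.14). HLA-DMB and CTSS, a protease of the class II pathway, gave -0.06 and -0.26. Without knockdown replicate 2 the list's adjusted p was 0.106 at a median of 0.12, and without the DRB genes 0.146 at a median of 0.11.

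The class I genes leaned the same way without passing. Their median was 0.09, with 16 of 18 members above 0 (camera adjusted p = 0.127, and 0.931 with an estimated correlation). HLA-G stood at 381 and 482 (0.33) and passed the intensity-trend fit (adjusted p = 0.0338), on probes that can match related class I transcripts, and NLRC5, the class I counterpart of CIITA, gave 28.4 and 36.5 (0.25, adjusted p = 0.404 there). With the intensity trend in camera the class I list passed (adjusted p = 0.00977). Factors of the class II transcription complex had a median of -0.02 (adjusted p = 0.978), with KAT2B at -0.40 and NFYC at 0.29. Checkpoint and costimulatory ligands had a median of 0.10 (adjusted p = 0.362), which lay between 0.06 and 0.14 with single arrays left out. CD48 stood at 164 and 249 (0.56), ICAM1, an adhesion ligand, at 335 and 470 (0.47), and CD70 at 239 and 303 (0.32), and these 3 passed the intensity-trend fit with adjusted p-values of 0.00333, 0.00332 and 0.0320. The gene of the checkpoint ligand PD-L1, CD274, read 20.4 ± 1.03 and 20.1 ± 0.88 (-0.01, adjusted p = 0.970). PDCD1LG2 lay below the filter on dim probe sets, with 5.62 against 2.86 and 4.61 against 7.45 at its probe sets.

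**Figure D3:**
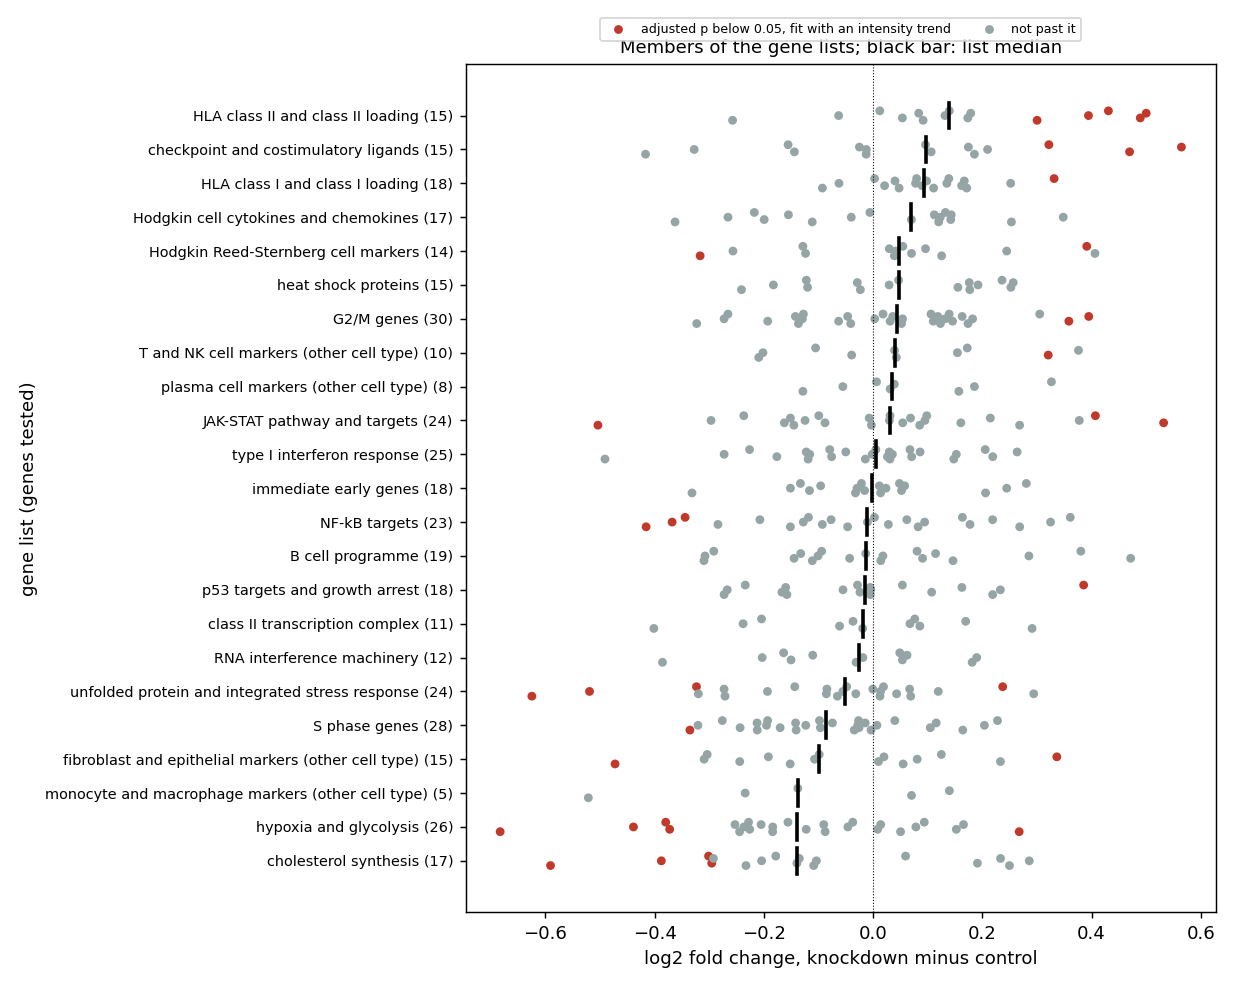
Log2 fold changes (knockdown minus control) of the tested members of 23 gene lists, 1 point per gene and a black bar at each list's median; members past the intensity-trend fit are red and the number tested is in brackets. The class II list has the highest median, 0.14, and the cholesterol, hypoxia and monocyte lists the lowest, -0.14 each.

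Among lists with lower medians, cholesterol synthesis genes stood at a median of -0.14 with 12 of 17 below 0 (camera adjusted p = 0.209, and 0.931 with an estimated correlation). Fry gave this list an adjusted p of 0.115, the same as for class II, and an unadjusted p of 0.00746 against 0.01 there. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, read 897 ± 87.2 and 589 ± 11.4 (-0.59), and lower knockdown means also held at its other probe sets (224 against 175, and 344 against 294). HMGCS1, an early enzyme of the pathway, read 572 ± 26.4 and 434 ± 32.6 (-0.39), and MSMO1 and FDPS gave -0.30 each. These 4 passed the intensity-trend fit, and the list passed camera with the intensity trend (adjusted p = 0.00977). Hypoxia and glycolysis genes had a median of -0.14 with 18 of 26 below 0 (camera adjusted p = 0.146, 0.931 with an estimated correlation, 0.0209 with the intensity trend). PFKFB3, a regulator of glycolysis, stood at 44.1 and 21.6 (-0.68), INSIG2 at 139 and 97.7 (-0.44), BNIP3 at 361 and 273 (-0.38) and PDK1 at 242 and 182 (-0.37), while PKM, pyruvate kinase, stood at 922 and 1111 (0.27). These 5 passed the intensity-trend fit. The controls differed between themselves in this list, by a median of -0.26 for replicate 1 minus replicate 2, against 0.00 for the knockdowns. Among 10000 random lists matched on brightness, the cholesterol and hypoxia medians lay at the percentiles 0.08 and 0, further out than class II at 99.5. Members of random lists were drawn independently, while the hypoxia genes varied together, with an estimated correlation of 0.58. For cholesterol and class II it was -0.06 and -0.03. The hypoxia percentile, and its camera p-values with a preset correlation of 0.01, therefore overstate the evidence. Without control replicate 1 the hypoxia list's median was -0.27, and without control replicate 2 it was -0.01. Genes of the unfolded protein and integrated stress response had a median of -0.05 (adjusted p = 0.391) and a median difference between the controls of -0.14. That list's median was -0.13 without control replicate 1 (adjusted p = 0.0223) and -0.01 without control replicate 2 (adjusted p = 0.926). ATF4, the transcription factor of the integrated stress response, stood at 715 ± 96.9 and 494 ± 61.7 (-0.52), the cystine transporter gene SLC7A11 at 53.7 ± 13.6 and 28.8 ± 2.64 (-0.62), and ASNS, asparagine synthetase, at 506 and 401 (-0.32), and the chaperone gene HSPA5 at 813 and 961 (0.24). These 4 passed the intensity-trend fit, with adjusted p-values from 0.00482 to 0.0373.

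Type I interferon response genes were not called as a group. Of 41 listed genes 25 were tested, with a median of 0.01 and 13 above 0 (camera adjusted p = 0.978), which does not exclude a response. XAF1 and RSAD2 stood at -0.49 and -0.27, passing neither fit. NF-kB targets had a median of -0.01 (adjusted p = 0.907), with REL at 218 and 165 (-0.37), TNFAIP3 at 249 and 182 (-0.42) and BIRC2 at 347 and 271 (-0.34) past the intensity-trend fit. Other probe sets did not all follow, with 114 and 119 (0.06) for TNFAIP3, and 135 and 139 (0.04) and 132 and 98.4 (-0.37) for REL. JAK-STAT genes had a median of 0.03 (adjusted p = 0.736). The common cytokine receptor chain IL2RG, at 113 and 171 (0.53), and IL21R, at 199 and 269 (0.41), were on the high side and IL13RA1, at 159 and 107 (-0.50), on the low side, all past the intensity-trend fit. The dimmer IL13RA1 probe sets read 24.2 and 31.0 (0.22), 28.3 and 32.9 (0.15) and 38.9 and 32.2 (-0.19). Cytokines and chemokines of Hodgkin cells had a median of 0.07 (adjusted p = 0.857), with CXCL9 at 0.35 and CCL20 at -0.27. Hodgkin Reed-Sternberg cell markers had a median of 0.05 (adjusted p = 0.493). FUT4, which makes the CD15 epitope, gave 0.39 and the actin-bundling protein gene FSCN1 -0.32, both past the intensity-trend fit, and IL2RA gave 0.41. A dimmer FSCN1 probe set read 27.9 and 39.3 (0.35). The B cell programme had a median of -0.01 (adjusted p = 0.907), with CD37 at 0.47 and CD24 at 0.38, and immediate early genes had a median of 0.00 (adjusted p = 0.907), with JUN at -0.33 and FOSL1 at 0.28.

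S phase genes had a median of -0.09 with 21 of 28 below 0 (adjusted p = 0.362). RFC4 gave -0.34, past the intensity-trend fit, and E2F1 gave -0.32. G2/M genes had a median of 0.04 (adjusted p = 0.493), with BIRC5 at 0.36 and CCNB1 at 0.39 past the intensity-trend fit. Above the filter, the other probe set of CCNB1 read 110 and 105 (-0.07), and those of BIRC5 38.6 and 62.3 (0.52), 28.5 and 38.7 (0.29) and 44.8 and 41.1 (-0.07). For p53 targets the median was -0.01 (adjusted p = 0.979), and CDKN1A, which encodes the cell cycle inhibitor p21, stood at 137 ± 2.66 and 185 ± 6.59 (0.39, past the intensity-trend fit), while AEN gave -0.27. Heat shock genes had a median of 0.05 (adjusted p = 0.493), with DNAJB4 at -0.24 and HSPB1 at 0.26. The RNA interference machinery had a median of -0.02 (adjusted p = 0.814), with AGO4 at -0.39 and PRKRA at 0.18. Of the markers of other cell types, those of T and NK cells had a median of 0.04 (adjusted p = 0.493), with CD3D at 188 and 239 (0.32, past the intensity-trend fit at 0.0499) and CD4 at 0.38. The T and NK median was 0.08 to 0.11 with single arrays left out, 0.09 with quantile normalization and 0.10 with median centring. Monocyte and macrophage markers had 5 tested members and a median of -0.14 (adjusted p = 0.493), with C1QC at -0.52 and ITGAM at -0.23. Plasma cell markers had a median of 0.04 (adjusted p = 0.493), with FKBP11 at 0.33 and DERL3 at 0.19. Fibroblast and epithelial markers had a median of -0.10 (adjusted p = 0.494), with COL1A2 at -0.47 and SPARC at 0.34, both past the intensity-trend fit. With single arrays left out the fibroblast and epithelial median lay between -0.08 and -0.01.

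In the common-prior fit no member of any list passed over all genes. When adjusted over the list alone, CD48 and ICAM1 passed on the high side and FASLG on the low side among the ligands, IL2RG high and IL13RA1 low among JAK-STAT genes, and FUT4 and IL2RA high among Hodgkin cell markers. INSIG1, PFKFB3, C1QC and COL1A2 passed on the low side in the cholesterol, hypoxia, monocyte and fibroblast lists, and 0 members passed in the 15 lists other than these and class II. The named genes and the list members past the intensity-trend fit were 86 genes. Another probe set above the filter existed for 39 of them, and for 17 at least 1 such probe set had a fold change of the opposite sign (BIRC5, CCNB1, CD74, CIITA, CSGALNACT1, FKBP11, FSCN1, HSPA5, IL13RA1, JUN, LINC02532, PDK1, PKM, PLEKHG2, REL, TNFAIP3 and XAF1). The medians of 8 lists, each near 0, changed sign under quantile normalization or with trends on gene length and brightness removed (type I interferon) or median centring (class II transcription complex, NF-kB, B cell, p53, stress response, immediate early and RNA interference lists). With 1 array left out, 6 further medians turned below 0, reaching -0.05 for JAK-STAT genes, -0.07 for plasma cell markers, -0.02 for Reed-Sternberg cell markers, -0.03 for G2/M genes, -0.01 for heat shock genes and -0.01 for Hodgkin cell cytokines. Without control replicate 2 the monocyte median was -0.04 and the plasma cell median 0.19.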

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

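The common-prior count of 2 genes, both lower, was also 2 with no filter, the lower quartile filter, quantile normalization, median centring, robust hyperparameters, every named probe set above the filter, thresholds of 0.01 and 0.10, and a fold threshold of 1. It was 1, lower, with the mean of probe sets, 0 with a pseudocount of 1, 387 (206 higher, 181 lower) with an intensity trend, and 406 (225 higher, 181 lower) with a pseudocount of 64, of which 364 were shared with the intensity-trend calls. Leaving out 1 array gave 1 to 6 calls, 0 to 1 higher and 1 to 5 lower, the lone array being assumed to vary like the others. KIF23-AS1 was called in every one of these settings except a pseudocount of 1, and PLEKHG2 in all except that one, the mean of probe sets (where its dim probe sets enter), and without either control. Over all 41091 named probe sets with no filter, each tested on its own, the common-prior adjusted p-values of KIF23-AS1 and PLEKHG2 were 0.0517 and 0.0518, so neither passed. With the intensity trend the adjusted p was 0.000173 for each there. PIERCE2 passed with the intensity trend (log2 fold change -0.58, adjusted p = 9.74e-05) and with a pseudocount of 64 (-0.55, adjusted p = 0.000406), and in no other setting that kept the common prior. Over all 41091 named probe sets its adjusted p was 0.0143 with the intensity trend and 0.454 with the common prior. A check added later, over all probe sets above the filter, named or not, also gave 2 calls. Causes were tested only for the gap between 2 and 387 calls, given among the other observations.

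Recomputing the intensity-trend count was chosen after the data were seen. It was 83 with no filter, 612 with median centring, 23 with the mean of probe sets, 82 and 716 at thresholds of 0.01 and 0.10, 4 with a fold threshold of 1, and from 142 to 377 with 1 array left out (142 without knockdown replicate 2, 143 without control replicate 2). Without knockdown replicate 1 the 377 were 119 higher and 258 lower. Median centring turned the split of 206 higher and 181 lower into 484 and 128, with 334 of the 387 genes kept, and quantile normalization into 157 and 190, with 320 kept. With the replicate number as a block the common-prior fit called 2 genes and the intensity-trend fit 1010. Same-numbered arrays did not deviate together (correlation -0.00668), so the numbers were not taken to pair the arrays. With 2 arrays per group both pairs give the same value by construction, so this is 1 correlation.

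The class II median of 0.14 lost its call without the DRB genes (median 0.11, adjusted p = 0.146) and without knockdown replicate 2 (median 0.12). With an estimated correlation its adjusted p was 0.931, in a form that hardly any list could pass with 2 residual degrees of freedom. With single arrays left out the median lay between 0.12 and 0.18. It kept its call with no filter, quantile normalization, median centring, the block, the intensity trend and both pseudocounts, at adjusted p-values from 0.000110 to 0.0181. With each array's trends on gene length and brightness removed, a setting added later, it was 0.11 (adjusted p = 0.0478). Beside it, the class I, cholesterol and hypoxia lists passed with the intensity trend and a pseudocount of 64, the class I list with no filter, and the hypoxia and stress response lists without control replicate 1. Of the 74 named genes tested, 44 beside KIF23-AS1 and PLEKHG2 passed with the intensity trend, and 44 beside them with a pseudocount of 64. How far low signal over background limits these comparisons was not tested.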

Other observations

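The gene families in the next paragraph, the genes SGO1 and CBS, the test on interferon genes, the class II median with trends removed and the splits of the arrays were chosen after values were seen.

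Genes for the mitochondrial translation and respiration machinery leaned to the knockdown side. The camera p-values in this paragraph were adjusted over the 7 added lists alone. They are descriptive, since these families were chosen after values were seen. Of 76 mitochondrial ribosomal protein genes, 60 lay above 0, with a median log2 fold change of 0.10 (quartiles 0.02 and 0.20). Camera gave an adjusted p of 2.58e-05 with the preset correlation of 0.01, and 0.514 with the estimated correlation of 0.15. The controls differed from each other by nearly as much in these genes, by a median of 0.09 for replicate 1 minus replicate 2. Of these, 7 passed the intensity-trend fit, all higher, among them MRPL12 (191 and 275, log2 fold change 0.49) and MRPS12 (145 and 203, 0.44). All 7 tested genes of the mitochondrial genome lay above 0, with a median of 0.21 (adjusted p = 0.00131, 0.470 with an estimated correlation). ND2, a subunit of respiratory complex I, read 1375 and 2052 (0.57, adjusted p = 3.49e-05 in the intensity-trend fit) and ND4 3338 and 3872 (0.21, adjusted p = 0.0219). The 77 nuclear genes of the respiratory chain had a median of 0.05 (adjusted p = 0.0113, 0.594 with an estimated correlation), and the controls differed by a median of 0.05 there, against 0.02 for the genes of the mitochondrial genome. Cytosolic ribosomal protein genes, by contrast, had a median of -0.03 over 57 genes (adjusted p = 0.839), which turned to 0.03 with median centring. The 310 zinc finger genes with ZNF symbols had a median of -0.06 (adjusted p = 0.0853). The medians of the 3 mitochondrial families stayed above 0 under quantile normalization (0.07, 0.20 and 0.03) and median centring (0.16, 0.27 and 0.11). Fry gave them adjusted p-values of 0.290, 0.219 and 0.290 in the same order. They were not retested with the trends on gene length and brightness removed.

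Among tested genes, the difference of largest size belonged to SGO1, a protector of centromeric cohesion, and rested on 1 array. It read 15.38 and 1654.5 in controls 1 and 2, and 16.01 and 13.35 in the knockdowns (log2 fold change -2.90, SE 1.56, adjusted p = 0.447). CBS read 5.49, 2.83, 2.23 and 94.0 in the same order of arrays (1.15, SE 0.71, adjusted p = 0.497).

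Higher class II genes were weighed against 3 technical accounts and 1 cellular one. A drift of scaling with brightness was argued against as the whole cause, because the list's median lay at the percentile 99.5 of 10000 random lists matched on brightness, and matching on gene length too gave 98.86. Removing both trends from each array lowered the median from 0.14 to 0.11 and left it just past the threshold (adjusted p = 0.0478, 0.00629 before), so part of the shift may follow them. A general interferon response to a hairpin stays open, since the type I interferon list lay at percentile 69.35 but 13 of its members were above 0 and 12 below, several of them dim. Sequence shared among DRB genes may account for part of the shift, since the median of the 12 members without them was 0.11, at percentile 96.95 and just inside the upper limit of 0.12 for random lists. HLA-DRA gave 0.39 and 0.46 on its probe sets, while HLA-DQB1 gave 0.43 on its brightest probe set and 0.01 and 0.05 on 2 others. An effect of the knockdown stays open and untested, since these probe sets do not show how far the fusion transcript itself was lowered and 1 hairpin was used.

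The gap between 2 calls with a common prior and 387 with an intensity trend may come from the noise of dim genes. The residual SD in the fifth of genes with the lowest intensity was 2.14 times that among the brightest (0.189 against 0.0884), so that a shared prior was wide for bright genes. A trend of fold change with gene length or brightness was argued against as the whole cause, since 380 genes passed after both trends were removed from each array, 343 of them among the 387. The balance turned, with 183 higher and 197 lower after removal against 206 and 181 before. The 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05. The real split, 1 of the 3, gave 387 calls against at most 0 in the others. In the other splits each group held 1 control and 1 knockdown, so any difference between knockdown and control entered the residual variance. Their lack of calls is therefore no reference for chance. No biological explanation was tested for this gap.

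Lower sterol genes, and the lower stress genes ATF4, ASNS and SLC7A11, were compared with further genes of the same responses. These further lists were chosen after the fixed ones, and their members were picked without their values. The cholesterol list's own median of -0.14 lay at percentile 0.08 of matched random lists. The fixed stress list's own median of -0.05 lay at percentile 6.72, inside the random range of -0.07 to 0.09, so that list as a whole was not shown to be lower. The 15 other SREBP targets had a median of -0.04 at percentile 23.86, with 6 above 0 and 9 below and quartiles of -0.13 and 0.11, too wide a spread to exclude lower SREBP activity. The 22 other amino acid response genes had a median of -0.07 at percentile 3.58, close to the lower limit of -0.07 for random lists, which leaves a lower amino acid response open as a possible explanation of the ATF4, ASNS and SLC7A11 values. The controls differed from each other in those 22 genes by a median of -0.10, and an effect of the knockdown itself stays untested.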
